A study of Mus musculus with 12 samples.

How the data were processed

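Total RNA from isolated mouse islets was hybridised to one-colour Agilent arrays labelled with Cy3, 1 array per sample, with 12 arrays in 4 groups of 3. The groups were wild-type (WT) and Uox-knockout (KO) males aged 8 weeks that received no injection, and WT and KO males aged 11 weeks that received streptozotocin (STZ-WT and STZ-KO). Groups and replicate numbers were taken from the sample titles. The labels number the replicates but do not say whether each came from a separate animal or from pooled islets, so the p-values measure only the spread between these samples, which may be partly technical.

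The deposited table holds 1 log2 value per probe and array, already normalized by the authors, for 56605 probes. Per the submitters' processing notes, Agilent Feature Extraction 10.7, limma and R 3.4.1 were used. How they were applied, the background correction and the normalization are not given in the sources used here. The log base was taken from the values, which ran from 1.54 to 18.6 and as natural or decimal logarithms would exceed any scanner range. The deposited table carries no detection or saturation flags, so whether a dim probe was above background is unknown, and folds of probes near the lower end may be understated. The 6 arrays without STZ had nearly the same minimum and maximum, and so had the 6 arrays with STZ, but these sets differed from each other, as after a normalization run on each set by itself. Levels were therefore compared directly only within a set, and STZ comparisons are given both on the deposited scale and after quantile normalization of all 12 arrays. Slide, scan date and hybridisation batch were not analysed here.

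The files do not pair probe identifiers with genes, so results are given per probe. No gene, including Uox itself, was named or checked, and the 30 gene lists fixed in advance were not tested. A probe may stand for any transcript, and several probes may report one gene. A second deposited table holds the authors' own numbers of differential genes at p-value thresholds of 0.01 and 0.05, for 4 comparisons between groups coded g1 to g4. It does not say which group each code stands for, or whether the p-values were adjusted.

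A probe was kept if it exceeded the 40th percentile of the array on at least 3 of the 12 arrays, which left 38996 probes. The main test was a limma 3.58.1 fit (lmFit and eBayes, R 4.3.3) of the 4 group means over all 12 arrays, with two-sided tests, Benjamini-Hochberg adjustment over all kept probes and a call at an adjusted p under 0.05. The groups share one estimate of the spread in this fit. The 5 comparisons were KO against WT, STZ-KO against STZ-WT, STZ-WT against WT, STZ-KO against KO, and the interaction (the difference between the last pair of STZ responses). Residual SD means the SD, over kept probes, of an array's deviations from its group mean. Principal components and array correlations used quantile-normalized values. Correlations of log2 differences are across probes, which are not independent replicates, and carry no p-value.

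The following alternatives were fixed before the data were examined: quantile normalization, centring on the 75th percentile, no filter, the upper 50% of probes by mean, eBayes with trend and robust settings, a fit of only the compared groups, the replicate number as a block, array weights, leaving out each array in turn, and 2 other thresholds. Averaging probes per gene and the tests of gene lists were also planned and were not run. The rule for named items, also fixed in advance, took a set of islet genes and, in each comparison, the 8 largest rises and falls among called items whose groups did not overlap (for the interaction, without this last condition). As the probes carry no gene names, the islet genes are not reported, 2 rises and 2 falls of KO against WT are given by identifier, and the others as ranges.

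The arrays were treated as unpaired. No 2 arrays held identical values. Leaving out an array that leaves 2 in its group assumes that they vary like the other groups.

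The fits were tested on simulated arrays of the 38996 probes, with 200 changed probes. Each probe was drawn with its limma spread from the fit of 12 arrays, scaled to the measured spread of the group. The limma spreads are drawn toward a common value. Simulated spreads therefore vary less between probes than measured ones, which may raise the share called. For KO against WT, the fit of 12 arrays called 7% of the 100 probes changed by 1 on the log2 scale and 51% of the 100 changed by 2, with 16 false calls among 74, where the KO arrays were drawn with their larger spread and the fit shares one spread. The share of changes called and the share of false calls depend on the number of changed probes and hold only for this simulation. The fit of only the KO and WT arrays called 0% of either size. For STZ-KO against STZ-WT, the fit of 12 arrays called 1% and 45% with 0 false calls, and the fit of the 6 STZ arrays called 0% and 44% with 2 false calls. The number of arrays limits the precision.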

Results

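Gene expression was measured in pancreatic islets of male mice lacking Uox, the gene of urate oxidase, the enzyme that breaks down uric acid in mice, and of wild-type controls. Mice without this enzyme are a model of hyperuricemia. Both genotypes were studied without treatment at 8 weeks of age. Both were also studied after streptozotocin (STZ), a toxin taken up by insulin-producing beta cells, at a daily dose of 40 mg/kg for 5 days, with islets collected 16 days after the last dose at 11 weeks of age. Each of the 4 groups (WT, KO, STZ-WT and STZ-KO) held 3 arrays, and 38996 probes were tested. STZ animals were older than untreated animals, so STZ and age cannot be told apart, whereas the genotypes were compared at equal age.

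The deposited values of the STZ and the untreated arrays lay on different scales. The array median was between 4.01 and 4.02 on the log2 scale in the 6 untreated arrays and between 4.65 and 4.66 in the 6 STZ arrays, a difference of 0.64. The maximum was 18.34 on every untreated array and 18.57 on every STZ array. Within each of these sets the distributions were nearly identical.

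**Figure D1:**
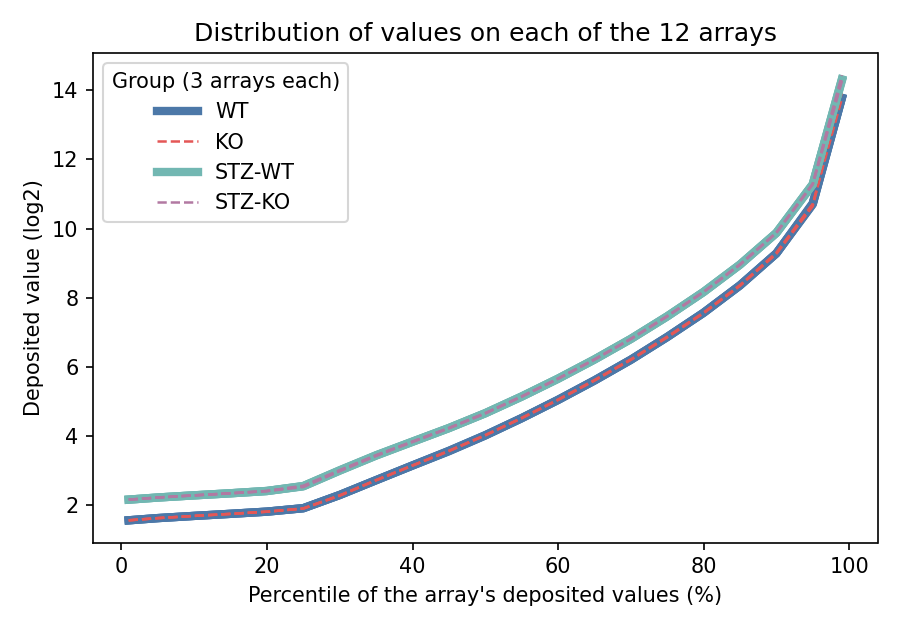
Deposited log2 value (vertical axis) at each percentile of the array's values (horizontal axis, %) for the 12 arrays, with solid lines for WT and STZ-WT and dashed lines for KO and STZ-KO. Arrays of the same treatment lie on top of each other, and the 6 STZ arrays run above the 6 untreated arrays, by 0.64 at the median.

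After quantile normalization of all 12 arrays, the first principal component held 47.4% of the variance and parted the STZ arrays from the untreated arrays. Component 2 (13.9%) parted KO from WT among untreated arrays, and component 3 (12.2%) spread the KO arrays, with KO replicate 1 at 171.8 and KO replicate 3 at -81.0. The STZ-WT and STZ-KO arrays lay together on components 2 and 3. Replicates correlated with r between 0.971 and 0.976 in WT, 0.974 and 0.977 in STZ-WT, 0.955 and 0.973 in STZ-KO, and 0.888 and 0.944 in KO. The KO arrays were the most variable group, with a residual SD of 0.697 ± 0.117 (SD, n = 3) against 0.390 ± 0.018 (SD, n = 3) in WT. All 3 KO arrays exceeded all 3 WT arrays (permutation test of these values, two-sided, p = 0.1, the smallest that 3 against 3 allows). Each value was taken from the mean of its own 3 arrays, so 1 outlying array raises the others. The 3 values of a group are not independent, and this p is only a description.

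**Figure D2:**
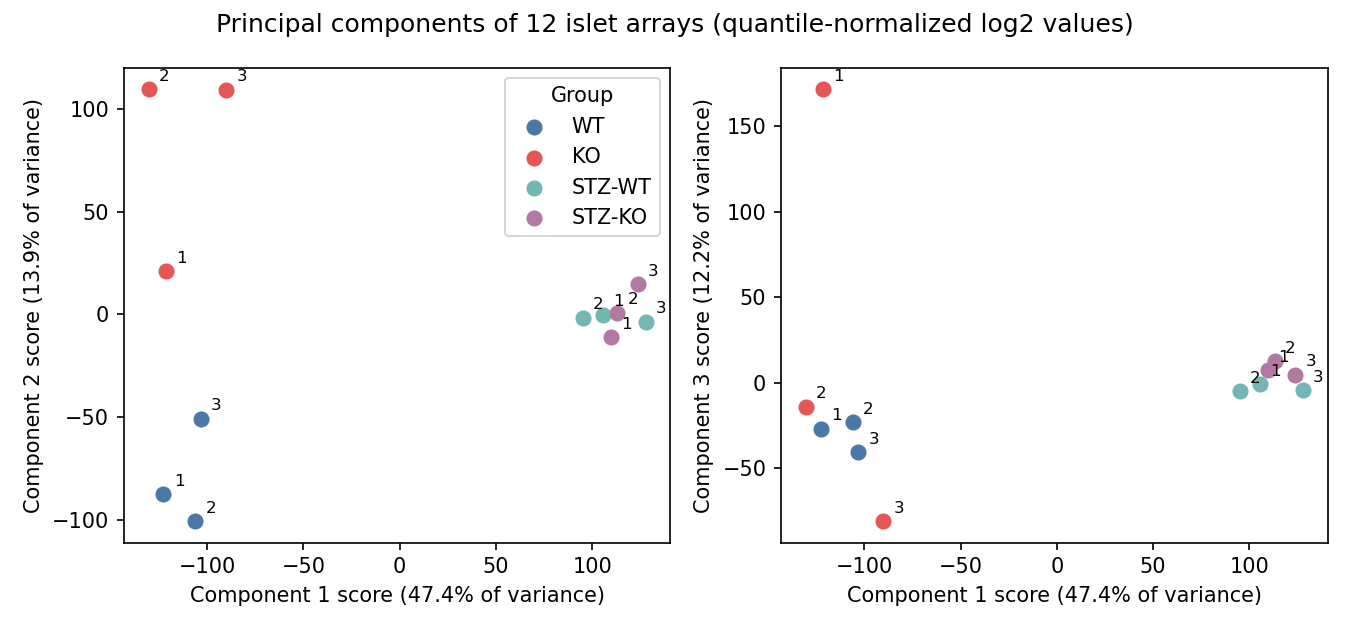
Principal component scores of the 12 arrays from quantile-normalized log2 values, component 1 (47.4% of variance, horizontal) against component 2 (13.9%, left panel) and component 3 (12.2%, right panel). Each point is 1 array, coloured by group and numbered by replicate; STZ arrays of both genotypes cluster together, while the 3 KO arrays lie apart from one another.

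Untreated KO islets were compared with untreated WT islets to measure the difference between genotypes without STZ. In the fit of all 12 arrays, 5596 probes (14.4%) differed, of which 2286 were higher and 3310 lower in KO, and 4353 of them differed at least 2-fold. Among the 8 largest differences in each direction, probes were between 19.2-fold and 97.8-fold higher, or between 11.7-fold and 21.6-fold lower, in KO, as ratios of deposited values that for dim probes are not shown to be above background. Differences were found at every brightness: 738 of the 9749 dimmest probes and 1778 of the 9749 brightest were called. Of the 1778, 627 were higher and 1151 lower in KO. Among the 100 brightest probes, 5 were lower and 0 were higher in KO, with log2 differences between -1.80 and 1.10 over all 100. The number of calls rested on the spread shared by the 4 groups, and in data simulated with the spread of these groups and 200 changed probes 16 of 74 calls were false. That share depends on how many probes change, so it does not measure the false share of the 5596. When only the KO and WT arrays were fitted, limma called 0 probes, with a smallest adjusted p of 0.0743. In that fit 9073 probes (23.3%) had an unadjusted p under 0.05, where chance gives 5%. With 200 changed probes, that fit also called 0% of simulated changes of 2 on the log2 scale. Recovery too depends on how many probes change. The simulation therefore does not show what that fit would call if many more did, and what its 0 excludes is not settled. With array weights 11760 probes were called. The count was 11169 without KO replicate 1, 3396 without KO replicate 2, 1604 without WT replicate 1 and 1114 without WT replicate 2.

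Probe A_55_P1998471 had the largest rise, with a log2 value of 12.23 ± 2.58 (SD, n = 3) in KO and 5.62 ± 1.33 (SD, n = 3) in WT, a log2 difference of 6.61 (SE 1.09, limma adjusted p = 0.00692). Probe A_51_P256827 stood at 10.31 ± 2.55 in KO and 4.08 ± 1.05 in WT, a 74.9-fold difference (limma adjusted p = 0.00780). The lowest WT value of A_51_P256827 was 3.15, near the 40th percentile of the WT arrays, between 3.14 and 3.15. Its WT level is therefore not shown to be above background, and its rise is not exact and may be understated. Probe A_51_P221510 had the largest fall, from 7.53 ± 1.34 in WT to 3.09 ± 1.70 in KO (limma adjusted p = 0.0105). Probe A_66_P101407 stood at 6.97 ± 0.37 in WT and 3.04 ± 1.18 in KO (limma adjusted p = 0.00257). The KO means of both lower probes lay below the 40th percentile of the KO arrays, between 3.14 and 3.15, and their lowest KO values were 1.76 and 1.73. These levels are therefore not shown to be above background. The falls of both probes are not exact and may be understated, and the 21.6-fold fall given above is that of A_51_P221510. The KO and WT arrays did not overlap for 32.0% of all probes, where chance gives 10% for 3 against 3. All 4 named probes lost their calls when only the KO and WT arrays were fitted.

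The same genotypes were compared after STZ. No probe was called between STZ-KO and STZ-WT in the limma fit of 12 arrays (0 of 38996, smallest adjusted p = 0.197), and 0 were called in the limma fit of the 6 STZ arrays alone. Without KO replicate 3 the count was 1, without STZ-KO replicate 1 it was 2, with array weights it was 3 and with no filter on dim probes it was 10. At an unadjusted p under 0.05 there were 1750 probes (4.49%) in the first fit, 695 of them higher and 1055 lower in STZ-KO, and 3153 (8.09%) in the second. The mean squared log2 difference between genotypes was 0.221, against 0.172 expected from the spread between replicates, whereas without STZ it was 0.745 against 0.324. Among the 100 brightest probes the log2 differences between STZ-KO and STZ-WT lay between -0.28 and 0.40, and 0 were called. The STZ-KO and STZ-WT arrays did not overlap for 5668 probes (14.5%), where chance gives 10%. In simulated data of this size about 45% of the probes changed by 2 on the log2 scale were called, and 1% of those changed by 1, with 200 changed probes, so most single probes changed by 1 would not have been called at that number.

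The probes called between KO and WT were also compared between STZ-KO and STZ-WT. They were chosen by their difference without STZ, which raises its median but not the median with STZ, so these medians do not measure how much of a difference was lost. The 2286 probes higher in KO had a median log2 difference of 1.27 without STZ and 0.02 between STZ-KO and STZ-WT, where 53.3% were higher in STZ-KO, against 47.6% of all probes. The 3310 probes lower in KO had medians of -1.31 and -0.06, and 61.9% were lower in STZ-KO, against 52.4% of all probes. Across probes the genotype differences without and with STZ, which share no array, correlated with r = 0.05 (Spearman's rho 0.08). This r lay between -0.002 and 0.088 when single arrays were left out, and its jackknife SD was 0.088. Noise lowers such an r. With STZ the mean squared difference was 0.221, of which the spread between replicates accounts for 0.172. A low r therefore does not show that the genotype effects are unrelated. Probe A_55_P1998471 stood at 7.42 ± 0.67 in STZ-KO and 7.59 ± 0.76 in STZ-WT (SD, n = 3 each), a log2 difference of -0.17 (SE 1.09). Probe A_51_P221510 stood at 5.68 ± 0.62 and 5.95 ± 0.62.

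**Figure D3:**
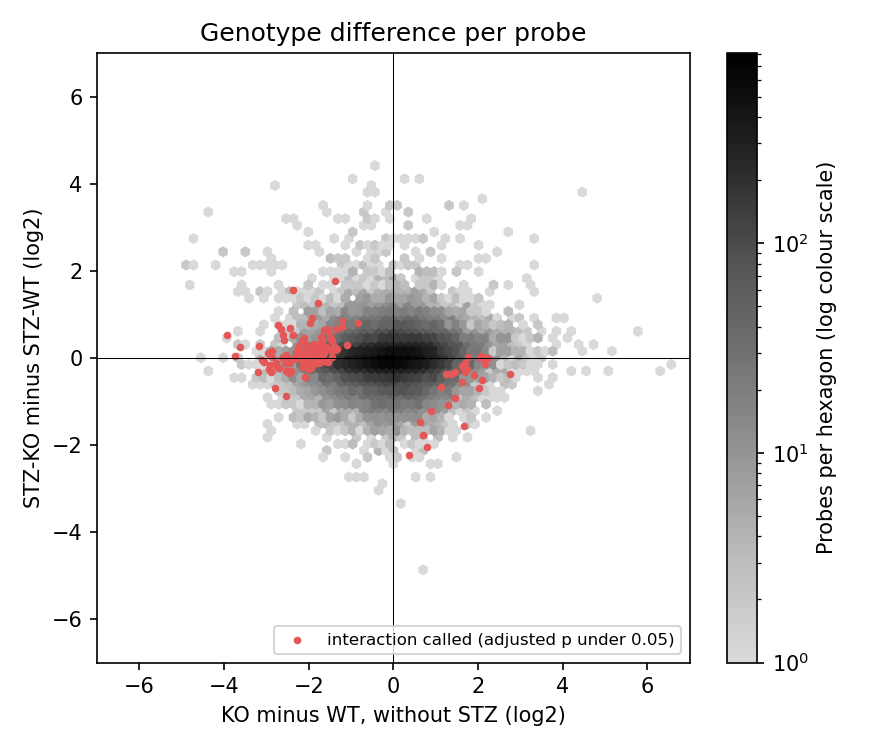
Genotype difference of each of the 38996 probes (log2) without STZ (KO minus WT, horizontal) and with STZ (STZ-KO minus STZ-WT, vertical); grey shading counts probes per hexagon on a log colour scale and red points are the 142 probes called for the interaction. The cloud is wider along the horizontal axis, and the median of the probes called in KO lies near 0 on the vertical axis.

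The difference between the genotype effects was tested as an interaction, in which the offset between STZ and untreated arrays cancels. It called 142 probes. For 114 of them the difference of STZ-KO from STZ-WT was above that of KO from WT. All 114 had been called lower in KO than in WT, with a median log2 difference of -2.09, and their median between STZ-KO and STZ-WT was 0.06. For the other 28 the interaction was negative, and all 28 were higher in KO than in WT, 24 of them called. Their median log2 difference was 1.68 without STZ and -0.38 between STZ-KO and STZ-WT. Selecting probes by the interaction by itself favours STZ differences away from those without STZ, so these medians do not show a reversal. The interaction also contains the difference of KO from WT on the same arrays. The directions and calls of these probes in KO are therefore no separate evidence. Of the 4 named probes only A_66_P101407 was called, with an interaction of 4.46 (SE 0.70, limma adjusted p = 0.0397). The KO levels of this probe and of A_51_P221510 are not shown to be above background, so their interactions are not exact and may be understated. The same holds for A_51_P256827 through its WT level. The call of A_66_P101407 was lost without any one of 10 of the 12 arrays, all but KO replicates 1 and 3, at interactions between 4.25 and 4.66. A_55_P1998471 had a larger interaction (-6.79, SE 1.55) and did not pass (limma adjusted p = 0.0777), but passed without KO replicate 1 (-6.33) or KO replicate 2 (-8.24). A_51_P256827 also passed without KO replicate 1 (-5.98) or 2 (-8.02), and A_51_P221510 without KO replicate 3 (5.12). The count changed by over 1.5 times without any one of the 12 arrays, from 1 without WT replicate 1, STZ-KO replicate 1 or STZ-KO replicate 2 to 5232 without KO replicate 1. It was 22 and 1149 without KO replicates 2 and 3, 4 without WT replicate 2 or 3, 3 without STZ-KO replicate 3, and 2, 6 and 6 without STZ-WT replicates 1, 2 and 3.

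The response to STZ was measured within each genotype, across the separately scaled sets of arrays. On the deposited scale, STZ-WT differed from WT in 15756 probes, 13151 higher and 2605 lower, and the median probe was 0.55 higher on the log2 scale. After quantile normalization 12268 probes differed, 5598 higher and 6670 lower, with a median of -0.05. STZ-KO differed from KO in 18961 probes on the deposited scale, 15274 higher and 3687 lower with a median of 0.65. After quantile normalization 14163 probes differed, 6959 higher and 7204 lower, with a median of 0.04. The direction of a probe is therefore given only after quantile normalization, that is, relative to the other probes. On that scale the 8 largest rises lay between 78.3-fold and 345-fold in WT and between 86.6-fold and 287-fold in KO. The 8 largest falls lay between 18.1-fold and 31.5-fold in WT and between 34.5-fold and 64.6-fold in KO. Among the 100 brightest probes, 2 were higher and 1 lower in STZ-WT than in WT, and 9 were higher and 8 lower in STZ-KO than in KO.

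The STZ responses of the genotypes overlapped. After quantile normalization 3480 probes were higher with STZ in both genotypes, where independent lists of these lengths would share 999, and 3936 were lower in both, where independent lists would share 1232. Of the probes called in WT, 11 that were higher and 91 that were lower were called in the opposite direction in KO. The responses correlated across probes with r = 0.70 (Spearman's rho 0.67), and r lay between 0.645 and 0.714 when single arrays were left out. These comparisons share no array, but they share the difference in age and in scaling. They also share one spread estimate per probe, which by itself can raise the shared counts above those of independent lists.

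The authors' deposited table lists their own numbers for 4 comparisons between groups coded g1 to g4. At a p threshold of 0.05, not stated to be adjusted, with a fold change of 2, the authors' deposited table gives 2559 for g2 against g1 (1099 up, 1460 down) and 8464 for g3 against g1 (3951 up, 4513 down). At those thresholds the authors' deposited table gives 5928 for g4 against g2 (2467 up, 3461 down) and 207 for g4 against g3 (33 up, 174 down). The codes were not matched to the 4 groups.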

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

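Tests chosen only after the result was seen were the ratio of residual SDs, the shares of probes in the fits of KO and WT alone and of the STZ arrays alone, the SD of the remaining KO pair, the offset of the array medians and all splits of the arrays; the others were written down before their own values were seen, but after the main counts, the array weights and unadjusted counts of the 2-group fits.

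A test of the difference itself called 142 probes whose genotype difference was not the same with and without STZ. Probe A_66_P101407 was one of them, with an interaction of 4.46 on the log2 scale, whose call was lost without any one of 10 of the 12 arrays. The KO level of this probe is not shown to be above background, so its interaction is not exact. Of 100 splits of the genotype labels within the STZ and within the untreated arrays, the real one included, 6 called as many probes. The highest of the others called 729. Of the others 9 called at least 1 probe, and their median was 0. A drawn split could keep the real KO and WT grouping and mix only the STZ arrays. Such a split carries the difference between KO and WT, so the share of splits does not measure chance. Chance is therefore not excluded for the interaction count. What produced the split with 729 calls, several times the real count, was not tested. A kept grouping of KO and WT and the unequal spread of the groups both stay open.

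The first pattern is that genotypes differed without STZ (5596 probes) while 0 probes were called with STZ. A single KO array as the source is argued against, since leaving out any of them left at least 3396 calls. Less precise STZ arrays are argued against, since their mean residual SD was 0.756 times that of the untreated arrays, KO included. It was 1.05 times that of WT alone. Many changes of 2 on the log2 scale hidden by the KO spread are argued against only as far as the simulation holds. The limma fit of the STZ arrays alone called 0 probes (3153 at an unadjusted p under 0.05). That fit called 44% of such changes in simulated data, where spreads vary less between probes, so the share may be too high. Smaller differences hidden in this way stay open, since that fit gave 8.09% of probes at an unadjusted p under 0.05 and the highest of the other splits 6.45%, and a KO spread underestimated by pooling stays open, since the fit of KO and WT alone gave 23.3% of probes at an unadjusted p under 0.05 and the highest of the other splits 10.9%, with 10 splits too few for a share under 0.05. A batch that followed genotype among the untreated animals, and an effect of Uox loss that differs with STZ or age, stay open as untested.

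For KO against WT, 1 of the 10 splits of the 6 arrays called as many probes, the real one with 5596, and the highest other called 21. For STZ-KO against STZ-WT all 10 splits called at least the real 0, which was fixed in advance, and the highest other called 1. For STZ-WT against WT 1 of 10 called as many, the real one with 15756, and the highest other called 0, and for STZ-KO against KO 1 of 10, the real one with 18961, and the highest other called 2. With 10 splits no share can fall under 0.05. Every other split mixes the groups, so a real difference enters its spread and lowers its calls. The highest other counts therefore do not measure what chance gives where no difference exists.

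Another pattern is the larger spread among the KO arrays. Noise of dim probes is argued against, since among the 9749 brightest probes the KO spread was 2.25 times that of WT, and 1.39 times among the 9749 dimmest. One outlying array as the whole source is argued against, since the SD between KO replicates 2 and 3 was 1.40 times the largest SD of a WT pair. Islet purity, RNA quality and variation between KO animals stay open and were not tested.

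The last pattern is the offset of 0.637 between the array medians of the STZ and the untreated arrays. A normalization run on each set by itself is a candidate cause, since medians within a set differed by at most 0.012. No biological explanation of the offset was tested, and STZ, age and a hybridisation of the sets apart cannot be told from it.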

How the results depend on the processing

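Across alternatives, the count of 5596 for KO against WT became 0 in a fit of only the compared groups, 11760 with array weights, 9291 at an adjusted p under 0.10 and between 1114 and 11169 without single arrays. It stayed within 1.5 times under the others, with 5247 under the replicate block. The count of 0 for STZ-KO against STZ-WT became 10 with no filter, 3 with array weights, 868 at an unadjusted p under 0.05 and at least 2-fold, and between 0 and 2 without single arrays. It was 0 under both other scalings, the upper 50% of probes, trend and robust settings, the replicate block, a fit of only those groups and an adjusted p under 0.10. STZ-WT against WT rose from 15756 to 23934 with no filter, where 56605 probes were tested, and STZ-KO against KO fell from 18961 to 12601 in a fit of only those groups. Centring on the 75th percentile gave 5727 higher and 6505 lower for STZ-WT and 7059 higher and 7111 lower for STZ-KO, close to quantile normalization. The interaction count of 142 became 625 with no filter, 485 in the upper 50% of probes, 305 with trend and robust settings, 2 under the replicate block, 6892 with array weights, 1420 at an adjusted p under 0.10 and 5792 at an unadjusted p under 0.05 and at least 2-fold. It lay between 1 and 5232 without single arrays and was 138 under both other scalings. Deviations of same-numbered arrays of different groups correlated between -0.14 and 0.23 over 18 pairs, 3 of them above 0.1, and 6 of 12 arrays correlated best with their own number, so the numbers were not taken to pair the arrays; the replicate block left 15438 calls for STZ-WT against WT and 18857 for STZ-KO against KO. Both correlations moved by less than their jackknife SD. For single arrays this was nearly fixed in advance, as that SD is computed from those same values. Centring and the replicate block left r unchanged by construction. Under quantile normalization, no filter and the upper 50% of probes, r lay between 0.047 and 0.050 for the genotype differences. For the STZ responses it lay between 0.667 and 0.713. Of 156 values of the named probes under alternatives, 133 kept direction and call, 15 lost and 8 gained a call, and 0 reversed. Of the 15, 11 were the interaction of A_66_P101407, 10 without single arrays and 1 under the replicate block. The named probes were chosen for KO and WT arrays that do not overlap, so leaving out 1 array could not reverse that difference. Several alternatives, such as leaving out an STZ array, cannot change it at all. These counts therefore say little about stability. The cause of each change was not tested. Averaging probes per gene, camera with either correlation and fry were not run, because no probe was assigned to a gene. Without background flags, what signal over background limits is unknown.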
